A study of Caenorhabditis elegans with 2 samples.

How the data were processed

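Whole L4 larvae of C. elegans strain OP432, which carries an eGFP-tagged zip-2 transgene, were profiled by ChIP-seq in 2 biological replicates with separate biosamples, both assigned to a single group by their labels. The labels name zip-2 as the target of the antibody and an eGFP fusion in the description, and they give no protocol of the immunoprecipitation. Fragment sizes of 150 to 350 are stated. The aligner, the peak caller and their versions are not given in the sources used here.

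Per the text files deposited with the samples, the authors called peaks on each replicate alone and on both pooled, in each case against a control alignment, and derived the IDR list from the pooled and replicate lists. The replicate and pooled lists are relaxed and include background, as input for IDR. Reads and the control itself were not analysed here, so the sequencing depth behind a peak is unknown. The deposited peak signal is the caller's own value, with a scale that is not stated, and was used only to rank and describe peaks within a list. The deposited −log10 q-value is capped in each list, and all 855 IDR peaks shared the cap of 3.37, as did 1180 pooled peaks, so it could not rank them. The third column used, other than these, is the authors' deposited summit offset. Most peaks had a fixed width, 390 bp for 763 of the IDR peaks. The 855 IDR peaks occupied 853 distinct intervals, since a wide interval can hold 2 summits, which were kept apart. Lists on assembly ce10 (813 IDR peaks) were used only for agreement between replicates, and no coordinate was converted.

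Positions are 1-based on ce11. Genes came from Ensembl release 115 (19973 protein-coding genes) and sequence from the RefSeq assembly of the same build. Each summit was placed in the first fitting class of promoter (1000 bp upstream of a protein-coding gene start), coding exon, untranslated exon, intron, non-coding RNA gene and intergenic. Shares were compared with 10000 sets of random positions, matched by chromosome, in a 2-sided permutation test. Chromosome counts were compared with assembled length in an exact binomial test. Motifs were searched on both strands within 100 bp of summits, and all 6-mers present in at least 5 windows within 50 bp, against windows centred 1000 bp to either side, with Fisher's exact test. Motif counts are over peaks, and flanks come from the same loci. A gene counted as occupied when a summit lay within 1000 bp of its start, and each of 28 gene lists was compared with all other protein-coding genes in Fisher's exact test. The collagen list was made from gene names (col, dpy, rol, sqt, bli and lon-3) and so includes genes that encode no collagen. The antimicrobial list was also made from names (lys, ilys, spp, nlp, cnc, abf and thn). It takes in all numbered nlp genes, neuropeptide genes among them. Tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg within each family at 0.05. Uniqueness was the share of 31-mers within 100 bp of the summit that are found once in the genome.

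The lists, motifs, tests, distances and most alternatives were chosen before the data were examined. Named are the 25 strongest IDR peaks with their nearest protein-coding gene start and a divergent start within 1000 bp, up to 4 members with the strongest peaks of each list that passed, zip-2, unc-119, irg-1 and irg-2, and the 5 6-mers with the highest odds ratio. Other genes, the 8-mers and the words on X were chosen after the values were seen. Alternatives were the 427 strongest IDR peaks, each replicate's 855 strongest peaks alone, other distances, windows, overlaps and backgrounds, and the ce10 lists. Added after seeing the data were the 1710 strongest pooled peaks, peaks shared with both replicates, autosomes or X alone, peaks without small RNA genes, genes with a relaxed peak as background, and the full replicate lists.

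The tests were checked on simulated peaks. Of 20 sets of 855 random positions, 0 were called for promoter share, 2 for any of the 28 gene lists and 2 for any 6-mer. These positions were uniform over the chromosomes, while the IDR summits gathered at promoters and differed in base composition. False calls that arise from such biases were therefore not measured. With 20 summits planted at ribosomal protein gene starts, the list was called in 20 of 20 sets, and an 8-mer planted at 40 of 855 summits ranked first in 20 of 20. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The precision of each share is limited by the number of peaks or genes, and with 1 group of 2 replicates no p-value describes variation between animals.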

Results

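ZIP-2 is a bZIP transcription factor that C. elegans needs for part of its response to pathogenic Pseudomonas aeruginosa. Here its chromatin occupancy was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L4 larvae, the last larval stage, of both sexes together. The strain OP432 carries an integrated eGFP-tagged zip-2 transgene in an unc-119 mutant background. The series held 1 group of 2 biological replicates, each with its own biosample, so no test between conditions was possible. The question addressed by the design is where in the genome the tagged protein was found. On assembly ce11, replicate 1 gave a relaxed list of 30000 peaks and replicate 2 gave 28784. The list called on both replicates pooled held 24669 peaks. The reproducible set, made with an irreproducible discovery rate (IDR) threshold, held 855 peaks, and these were the 855 strongest peaks of the pooled list. Their signal, a value the authors' caller gave each peak, ran from 48.4 to 1134 with a median of 65.2. Intervals given for shares are exact binomial 95% intervals over peaks or genes and cover counting error only.

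The strongest peak lay in the divergent promoter between irg-2, an infection response gene, and C49G7.10. It spanned chromosome V positions 4041793 to 4042543, with its summit at 4042055, 126 bp upstream of the irg-2 start and 34 bp upstream of the C49G7.10 start. It ranked first in both replicates, with a signal of 675 in replicate 1 and 447 in replicate 2. The peak ranked 5 lay on X 663 bp upstream of cebp-1, which encodes a C/EBP-type bZIP factor, and had a signal of 741. Close behind irg-2 came the promoter of Y58A7A.3 on V with a signal of 782, an intergenic site on X 2573 bp upstream of M163.11 with 780, and the promoter of eef-1A.2, a translation elongation factor gene on X, with 760. The site upstream of M163.11 lay within 500 bp of the snRNA gene M163.13.

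The 25 strongest peaks were all found among the 855 strongest peaks of each replicate. Of these, 12 lay on X, 8 on V and 13 on autosomes in all. On the autosomes 11 of the 13 lay within 1000 bp of a protein-coding gene start, against 3 of the 12 on X. The other autosomal sites next to starts were at E03H4.8, F13A7.11 with the divergent F13A7.12, cgp-1, nfx-1 with the ribosomal protein gene rps-13, fbxc-19 with fbxa-3, Y58A7A.5, F56D2.5, the nuclear hormone receptor gene nhr-58 and fbxa-37. The genes named fbxa and fbxc encode F-box proteins. The autosomal peaks nearest to F14F9.4 and CD4.11 were farther away, at 1092 and 2092 bp. On X, nspc-17 had a peak 710 bp upstream of its start. The remaining X peaks lay farther from their nearest starts, those of W02H3.3, ZK899.6, F55G7.5, K02D3.1, T27A8.7, gtr-1, cest-16 and xol-1, the gene that sets sex and X dosage early in development. The peak nearest to cest-16 was in an intron of mom-1, and the peak 4859 bp from xol-1 lay within 500 bp of a tRNA gene. Sequence around these 25 summits was largely unique, and the lowest share of unique 31-mers was 96.5%, at the CD4.11 peak.

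**Figure D1:**
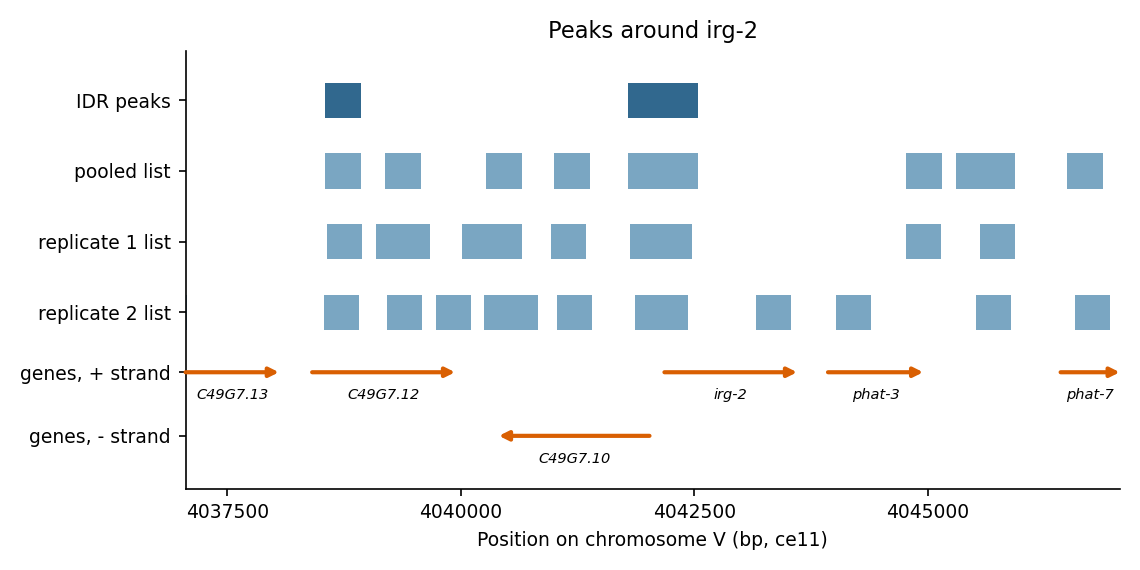
Peaks in 4 lists and protein-coding genes from position 4037055 to 4047055 of chromosome V, with boxes for peaks and arrows for genes in the direction of transcription. A box between C49G7.10 and irg-2 is present in each list, from 4041793 to 4042543 in the IDR and pooled lists, 4041812 to 4042477 in replicate 1 and 4041864 to 4042434 in replicate 2.

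Most IDR peaks were also among the strongest peaks of each replicate alone. Of the 855 IDR peaks, 649 (75.9%, interval 72.9 to 78.7%) overlapped the 855 strongest peaks of replicate 1 by at least 1 bp, and 647 (75.7%, 72.7 to 78.5%) those of replicate 2. Both replicates shared 492 of them (57.5%), and 51 were in neither. The 100 strongest were in both. Across the 851 IDR peaks with a counterpart in both full lists, the signals of the replicates had a Spearman rho of 0.448 and a Pearson r of log2 signal of 0.71. For each, a 2-sided permutation test gave p = 1e-05, the smallest that 100000 permutations can give. Overlap and correlation are both across peaks chosen for their pooled signal, and peaks are not independent replicates. Within the 427 strongest IDR peaks, 95.3% were shared with replicate 1 and 95.1% with replicate 2, which the selection on pooled signal favours by construction.

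**Figure D2:**
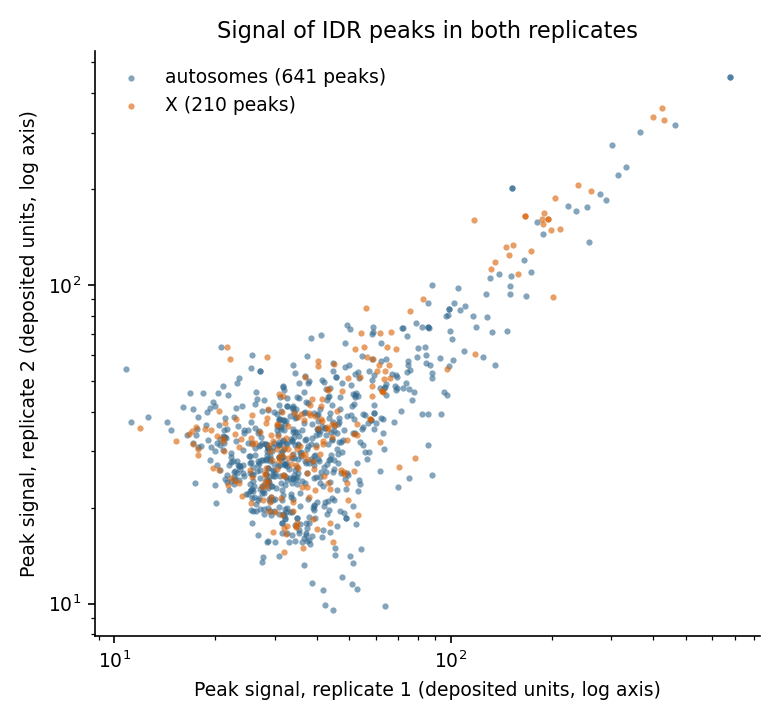
Signal of each of 851 IDR peaks in replicate 1 (x, deposited units, log axis) and replicate 2 (y, deposited units, log axis), with 210 X peaks in orange and 641 autosomal peaks in blue. The strongest peaks rise along the diagonal, up to 675 and 447 at irg-2, and the weaker ones scatter, with a Spearman rho of 0.448 over all.

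IDR peaks lay at promoters and next to small RNA genes far more often than random positions on the same chromosomes. Summits within 1000 bp of a protein-coding gene start made up 501 of 855 (58.6%, interval 55.2 to 61.9%), against 34.0% of random positions, a ratio of 1.72. In promoters, taken as the 1000 bp upstream of a start, lay 433 summits (50.6%) against 17.8%. Summits within 500 bp of a tRNA, snRNA, snoRNA or rRNA gene numbered 196 (22.9%, 20.1 to 25.9%) against 1.14%, a ratio of 20.2. Of these gene kinds, tRNA genes had 127 peaks next to them, snoRNA genes 56, snRNA genes 17 and rRNA genes 0. Such loci are frequent sites of unspecific ChIP signal. Whether the peaks there reflect binding of the tagged protein was not tested.

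Gene bodies held fewer summits. Coding exons held 3.04% of summits against 21.7% of random positions, and introns 18.6% against 31.5%. Annotated non-coding RNA genes held 4.56% against 0.787%, and intergenic sequence 19.3% against 24.4%. Untranslated exons, at 3.86% against 3.76%, did not differ (permutation p = 0.94). The permutation test over 10000 sets of random positions gave p = 0.0002, the smallest possible, for each other share except intergenic, where it was 0.0006. The relaxed peaks outside the IDR set were a closer background, with 39.6% of summits near a start and 2.59% near a small RNA gene. Fisher's exact test against them gave p = 6.9e-28 and p = 5.7e-111. Against that background the intergenic difference was not past the threshold (exact p = 0.19) and untranslated exons held fewer summits (5.96% in relaxed peaks, p = 0.0094).

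**Figure D3:**
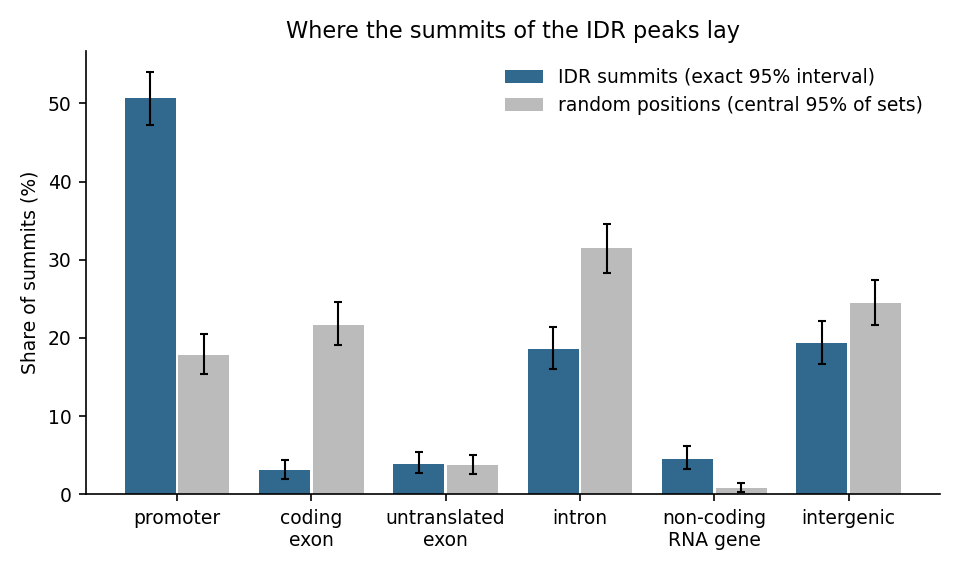
Share of the 855 IDR summits (blue) and of random positions on the same chromosomes (grey) in 6 classes of annotation, in percent. Whiskers are exact 95% intervals for summits and the central 95% of 10000 random sets for positions, and promoters hold 50.6% of summits against 17.8%, and coding exons 3.04% against 21.7%.

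The X chromosome held more IDR peaks than its length gives, and X peaks sat elsewhere than autosomal ones. X had 211 of the 855 peaks (24.7%, interval 21.8 to 27.7%) against 17.7% of the assembled length, a ratio of 1.40 (exact binomial test, exact adjusted p = 1.7e-06 over 6 chromosomes). Chromosome III also held more (ratio 1.28, exact adjusted p = 0.0025), while IV (0.711, exact adjusted p = 1.8e-04) and V (0.802, exact adjusted p = 0.0037) held fewer. Chromosomes I (0.988) and II (0.898) did not pass. Of the 211 X peaks, 39.3% lay within 1000 bp of a protein-coding gene start, against 64.9% of the 644 autosomal peaks (Fisher's exact test, adjusted p = 6.8e-10 over 8 measures). Next to small RNA genes lay 38.4% of X peaks and 17.9% of autosomal peaks (exact adjusted p = 8.3e-09). Untranslated exons held 0 of the X summits and 33 of the autosomal ones (exact adjusted p = 1.5e-04). Random positions differed in the same direction for gene starts (28.7% on X, 35.7% on autosomes) and small RNA genes (1.63% and 1.00%). For untranslated exons they went the other way (4.35% and 3.63%). Fisher's exact test compared the raw shares, without correction for these differences between chromosomes. Of the 612 annotated tRNA genes, 276 (45.1%) are on X. Without the peaks next to small RNA genes, a set chosen after seeing the data, 130 of 659 peaks were on X and the ratio was 1.12 (interval 0.948 to 1.30, exact adjusted p = 0.23). Against the share of relaxed peaks per chromosome, the ratios of III (1.12) and V (0.992) did not pass.

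Sequences of the C/EBP type and several GC-rich words were more frequent at summits than in flanking windows of the same loci. Of the 12 motifs fixed beforehand, 5 passed. The C/EBP palindrome TTGCGCAA lay within 100 bp of 2.22% of summits against 0.468% of flanks (exact adjusted p = 6.1e-04). The degenerate C/EBP-type site TTRCNYAA lay at 14.6% against 9.65% (exact adjusted p = 0.0011). A GAGA repeat lay at 6.20% against 1.05% (exact adjusted p = 9.5e-12), the E-box CACGTG at 7.13% against 4.27% (exact adjusted p = 0.0077), and TTACGTAA, the site of PAR and NFIL3 type bZIP factors, at 4 summits and 0 flanks (exact adjusted p = 0.029). The 7 others did not pass, among them the AP-1 site (2.46% against 1.23%, exact adjusted p = 0.061), CRE (1.75% against 0.936%), GATA (5.50% against 3.86%), the SP1 or KLF site (0.702% against 0.175%), the HSF repeat (1.75% against 1.46%), the C/EBP-ATF composite (0.702% against 1.11%) and a tract of T (3.63% against 4.09%). The C/EBP-type site went with strength: it was present in 23.4% of the strongest quartile of peaks and 9.86% of the weakest (Fisher's exact test, adjusted p = 0.0012). The palindrome was present in 3.74% and 0% (exact adjusted p = 0.018). The GAGA repeat (3.74% and 6.10%, exact adjusted p = 0.34), the E-box (3.74% and 7.51%, exact adjusted p = 0.16) and TTACGTAA (0.935% and 0.469%, exact adjusted p = 1) did not pass. The TTACGTAA call was lost under several settings, and the E-box call on autosomes alone and among the stronger peaks.

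Among all 2080 6-mers, 348 were enriched within 50 bp of summits and 238 depleted (Fisher's exact test, Benjamini-Hochberg adjustment). The 5 with the highest odds ratios were GCGCGC (9.39), CCCGGG (8.65), CACGCG (8.47), CGCGCA (8.12) and CGGCCG (7.33). The smallest p was that of ACGCAG, at 12.9% of summits against 2.16% of flanks. Neither flanks nor relaxed peaks were matched for base composition. AT-rich words were depleted against relaxed peaks, such as AAAATT at 21.8% of IDR summits against 45.4%. The 6-mer counts, and the motif counts above, therefore do not separate single words from a shift in base composition. With 8-mers, a word length chosen after seeing the data, TTGCGAAA came first, at 66 summits (7.72%) against 0.760% of flanks (exact adjusted p = 2.1e-16). The 1679 other words of the same bases lay at a median of 1 summit and at most 52, though TTGCGAAA was picked for coming first. It resembles the palindrome but matches neither C/EBP motif above. Within 100 bp it lay at 86 summits (10.1%), from 19.6% of the strongest quartile to 3.29% of the weakest (exact p = 7.4e-08). Among the 25 strongest peaks 11 held it, irg-2 and cebp-1 included.

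Genes of protein synthesis stood out among the 670 of 19973 protein-coding genes (3.35%) with a summit within 1000 bp of the start. Ribosomal protein genes came first, with 32 of 79 occupied (40.5%, interval 29.6 to 52.1%, exact adjusted p = 2.7e-25), and the strongest peaks among them were at rps-13 (signal 476), rpl-3 (337), rpl-20 (258) and rpl-15 (200.2). Translation factor genes had 12 of 42 occupied (28.6%, exact adjusted p = 1.1e-07), led by eef-1A.2 (760), ifet-1 (142), eif-6 (103.5) and eef-1A.1 (83.5). Aminoacyl-tRNA synthetase genes, which charge tRNAs, had 7 of 32 (21.9%, exact adjusted p = 4.2e-04), led by dars-1 (161), sars-1 (126), nars-1 (78.3) and aars-2 (68.3). Mitochondrial respiration genes had 12 of 57 (21.1%, exact adjusted p = 2.3e-06), led by cox-5A (172), ucr-2.2 (79.8), nduf-6 (78.3) and cyc-1 (78.2). Some of these genes share a peak: the summit counted for nduf-6 is that of nars-1, which lies nearer, and the summit counted for ifet-1 lies nearer to the ribosomal protein gene rps-1.

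Heat shock genes and, less firmly, the lists of 2 unfolded protein responses were also occupied more often than other genes. Cytosolic heat shock genes had 8 of 22 occupied (36.4%, interval 17.2 to 59.3%, exact adjusted p = 2.3e-06), with peaks at hsp-90 (signal 147), the constitutive chaperone gene hsp-1 (132), hsp-110 (121) and dnj-13 (99.8). The summit counted for hsp-110 lies nearer to the proteasome gene rpn-3 (185 bp against 259 bp). That of hsp-90 lies inside the gene, 891 bp from its start. The mitochondrial unfolded protein response list had 4 of 20 (exact adjusted p = 0.018): hsp-60 (118), ubl-5 (63.8), tomm-20 (58.4) and gpd-2 (49.6), the last a glycolytic enzyme gene. The endoplasmic reticulum list had 4 of 22 (18.2%, exact adjusted p = 0.020): xbp-1, its transcription factor (97.4), pdi-6 (65.6), enpl-1 (61.6) and pdi-3 (59.7). Both unfolded protein response calls were lost under other settings, such as a distance of 500 bp. Of the 28 lists 7 were enriched and 2 depleted. Of the 7, 5 stayed past the threshold with the other peak sets, distances, gene assignments and backgrounds tried, apart from peaks split by TTGCGAAA. These were the ribosomal protein, translation factor, aminoacyl-tRNA synthetase, mitochondrial respiration and heat shock lists. By peaks without TTGCGAAA the synthetase genes (3 of 32) did not pass. By the fewer peaks with it, the translation factor, mitochondrial respiration and heat shock lists did not. The shares moved, however: with each summit given to its nearest start only, ribosomal protein genes fell to 16 of 79 (20.3%) and heat shock genes to 4 of 22 (18.2%), and with the 492 peaks of both replicates, ribosomal protein genes fell to 24.1% and mitochondrial respiration genes to 10.5%.

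Immune effector genes had few peaks. C-type lectin genes had 1 of 240 occupied (0.417%, exact adjusted p = 0.020), clec-126 with a signal of 77.0. Lysozyme, saposin-like and other antimicrobial genes had 0 of 140 (upper limit 2.60%, exact adjusted p = 0.049). That list was picked by gene name and holds all numbered nlp genes, neuropeptide genes among them. Its call is therefore not one about antimicrobial genes alone. Both depletion calls were lost under several alternatives, among them genes with a relaxed peak as background. Of the infection response genes 1 of 8 had a peak, irg-2 (exact adjusted p = 0.51), of the pals genes 1 of 38, pals-24 (63.1), and of the p38 MAPK immunity list 2 of 20, cebp-1 and the pseudokinase gene nipi-3 (121, exact adjusted p = 0.34). Of the bZIP genes 3 of 29 had a peak, cebp-1, xbp-1 and jun-1 (52.9, exact adjusted p = 0.20).

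The marker lists of 5 tissues, intestine, muscle, epidermis, neuron and germ line, had 0 occupied genes among 30, 24, 21, 27 and 26. Oxidative stress genes had 0 of 24, vitellogenin genes 0 of 6 and major sperm protein genes 0 of 31. None of these lists passed. Their upper limits ran from 11.2% for major sperm protein genes to 45.9% for vitellogenin genes, above the 3.35% of all protein-coding genes. Lists this short therefore do not show that such genes lack peaks. Occupied were 9 of 190 cytochrome P450 and transferase genes, 2 of 34 proteasome genes, 7 of 269 nuclear hormone receptor genes, 1 of 89 homeobox genes, 4 of 195 genes with collagen-type names, 1 of 72 histone genes and 3 of 31 autophagy and lysosome genes, none past the threshold. The collagen-type list was picked by gene name and holds other genes too, such as dpy-23, an adaptor protein gene and 1 of its 4 occupied members. In the 7 lists with at least 5 peaks, the peaks' median signal percentile did not differ from random sets of IDR peaks. The largest median, 78.1 for the heat shock genes, had an adjusted permutation p of 0.38.

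**Figure D4:**
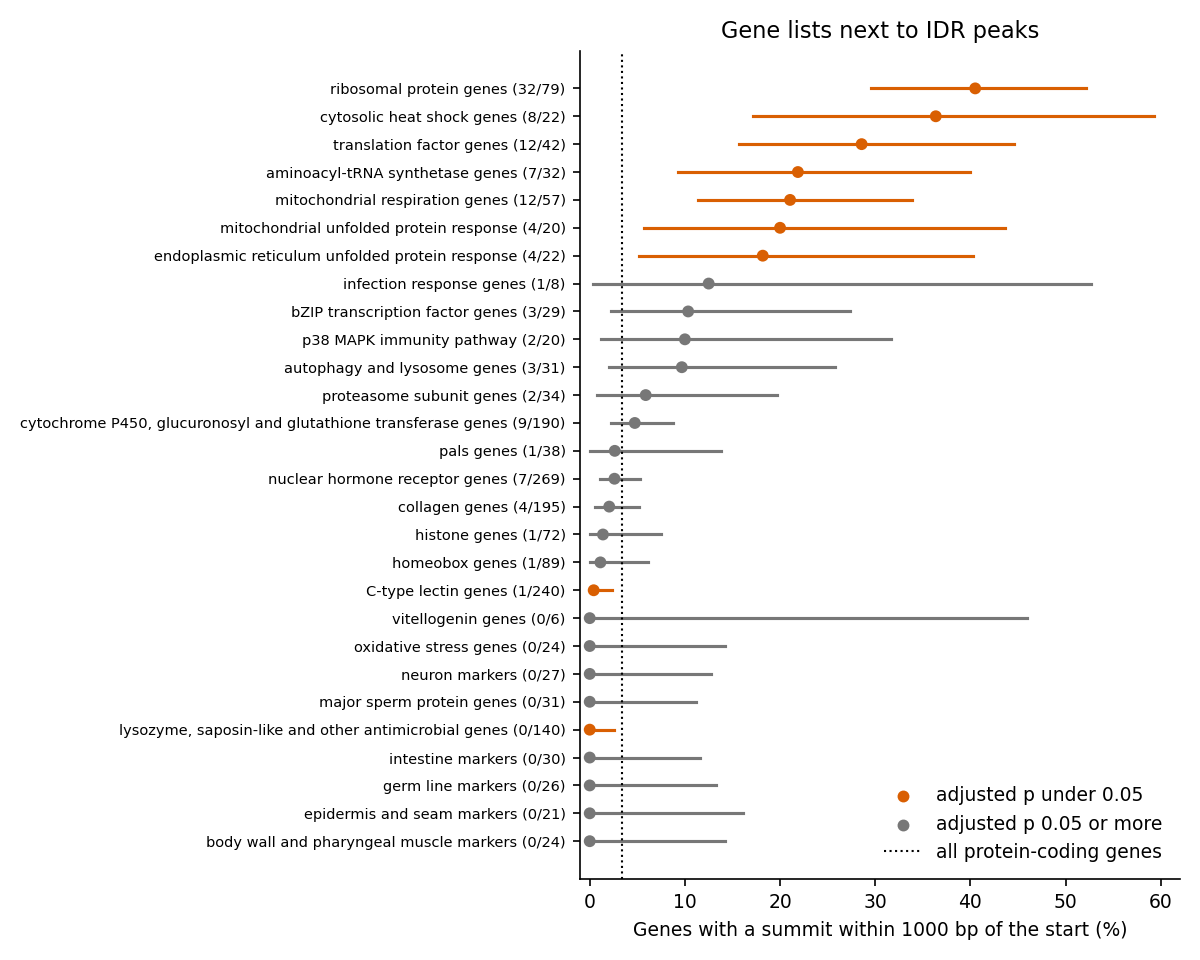
Share of genes with an IDR summit within 1000 bp of the start (x, percent) for the 28 gene lists fixed beforehand, with occupied and total genes in brackets and exact 95% intervals. Orange lists passed an adjusted p of 0.05, the dotted line is the 3.35% of all protein-coding genes, and ribosomal protein genes lie highest at 40.5%.

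The genes zip-2, unc-119 and irg-1 had no IDR peak within 5000 bp, while irg-2 had the strongest of all. The first of these encodes the tagged protein, and the second carries the mutation of the strain. At zip-2 the pooled list had no peak of any strength over 60030 bp, so the absence there does not show that the protein was absent. In the lists used here, no peak in any of the 4 had its summit within 5000 bp of zip-2 (chromosome III, 832982 to 835814). The same held for the IDR list around unc-119 (chromosome III, 10902641 to 10908935), while the relaxed lists had 5 peaks there in the pooled list, the strongest ranked 6733, 7 in replicate 1 and 0 in replicate 2. For irg-1 (chromosome V, 3523587 to 3524679), an infection response gene known to depend on zip-2, the strongest pooled peak within 1000 bp of the start ranked 18143 of 24669, and the strongest within 5000 bp of the gene ranked 1819. These ranks lie below the 855 of the IDR set. Around irg-2, by contrast, 3 IDR summits lay within 5000 bp.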

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

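The 74 results were recomputed under other settings, and 444 of 546 values kept their direction and side of the threshold, or, where no test applied, stayed within 1.5 times (counts) or within the interval (shares with a replicate). Results that did not pass counted as kept when they again did not pass in the same direction. Only 41 of the 74 results were kept in every alternative. The 1710 strongest pooled peaks, peaks shared by both replicates, autosomes or X alone, peaks without small RNA genes, genes with a relaxed peak as background, the full replicate lists and the 8-mers were chosen after seeing the data. The 855 strongest pooled peaks are the IDR set, so that setting was void and is left out of these counts. Leaving out a replicate was not possible for agreement between replicates, and no paired analysis was possible because there is 1 group. Depth could not be varied. Promoter share stayed 1.32 to 2.52 times its background, small RNA genes 8.85 to 20.2 times, and rank agreement at a rho of 0.420 to 0.548. Where no cause is given below, the cause was not tested. Values for gene lists are percentage points of occupied genes, list minus others, those for motifs are summits minus background, and those for chromosomes and classes are ratios.

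Sharing with replicate 1 and 2 was 95.3% and 95.1% for the 427 strongest IDR peaks, 91.5% and 91.0% against the 1710 strongest replicate peaks, and 99.9% and 99.6% against full lists, which hold more peaks to meet.

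Among the 427 strongest IDR peaks, calls ended for chromosomes III (1.21) and V (0.842), C-type lectins (-1.43) and antimicrobial genes (-1.85). They also ended for the mitochondrial (3.17) and endoplasmic reticulum (7.27) unfolded protein responses, TTACGTAA (0.468) and the E-box (0.351). GATA turned from 1.64 to -0.585. Fewer peaks were tested, but some effects shrank too. The odds ratio of the E-box fell from 1.72 to 1.09 and that of the mitochondrial response from 7.24 to 2.82. That of the endoplasmic reticulum response moved less, from 6.43 to 5.38. Enriched motifs were 3 and depleted lists 0. Among the 492 peaks of both replicates, calls ended for V (0.818), lectins (-1.65), antimicrobial genes (-2.06), the mitochondrial response (7.97), TTACGTAA (0.610) and the E-box (2.44), and pals genes (0.590) and the C/EBP-ATF composite (0.102) turned. Enriched motifs were again 3 and depleted lists 0.

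Among the 1710 strongest pooled peaks, bZIP genes (14.7), autophagy genes (13.3), GATA (2.98), the SP1 or KLF site (0.789), the T tract (-1.73) and untranslated exons (1.42) passed. Antimicrobial genes (-2.48) and TTACGTAA (0.234) no longer did, leaving 1 depleted list. Chromosome II (1.01), cytochrome P450 and transferase genes (-0.251) and histone genes (5.09) turned. Against relaxed peaks, III (1.12), V (0.992), intergenic sequence (0.908) and TTACGTAA (0.308) did not pass, untranslated exons (0.648) and GATA (-0.315) turned, the T tract passed (-3.35), and enriched 6-mers were 550. Without peaks at small RNA genes, V (0.880) and X (1.12) did not pass and I turned (1.05). On autosomes the AP-1 site passed (1.48) and the E-box did not (1.48). In 50 bp windows the T tract passed (-1.35) and TTACGTAA did not (0.234). X alone gave 118 6-mers and 15 8-mers, fewer peaks being tested, relaxed peaks 876 8-mers, and the strongest quartile 52, against 268.

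For gene lists, a distance of 500 bp ended the calls of lectins (-2.04), antimicrobial genes (-2.45), the mitochondrial (12.58) and endoplasmic reticulum (11.2) responses and turned pals genes (0.199). At 2000 bp antimicrobial genes (-3.64) and the mitochondrial response (14.97) did not pass. With the nearest start only, lectins (-2.10), antimicrobial genes (-2.51) and both responses (12.5 and 11.2) did not, and pals genes turned (0.143). Ribosomal protein genes fell from 40.5% to 20.3% occupied there and heat shock genes from 36.4% to 18.2%, both still past the threshold. With shared summits counted once, and for the list where a list gene shared them, lectins (-2.10) and antimicrobial genes (-2.51) did not pass. In that setting pals (0.141) and nuclear hormone receptor genes (0.113) turned. Among genes with a relaxed peak, lectins (-5.66), antimicrobial genes (-7.96) and both responses (14.3 and 15.7) did not pass, and pals (4.60) and proteasome genes (-0.214) turned. Depleted lists were 0 in each but 1 at 2000 bp. The signal percentile of mitochondrial respiration genes turned to 5.03 over random in replicate 1, and that of nuclear hormone receptor genes to -14.2 in replicate 2.

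From 1 replicate alone, ranges over both were 1.27 to 1.52 for untranslated exons, past the threshold in replicate 1, 0.175 to 0.468 for TTACGTAA, lost in replicate 2, and 0.468 to 0.702 for the SP1 or KLF site, past it in replicate 2. They were 0.936 to 1.17 for AP-1 and 0.643 to 3.98 for GATA, both past it in replicate 1. The C/EBP-ATF composite (0 to 0.0585) and the T tract (-1.46 to 1.05) turned in replicate 1. Depleted lists were 1 in each. Antimicrobial genes (-3.34 to -3.19) and the mitochondrial response (11.7 to 11.8) lost their calls in both, and bZIP (7.04 to 10.6) and autophagy genes (9.60 to 9.75) passed in replicate 2 alone.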

Other observations

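The tests of X peaks by the 12-base element, of X peaks without small RNA genes and against relaxed peaks, of growth genes, of F-box genes and of TTGCGAAA peaks were chosen after the result was seen, and those of small RNA genes and repeats at the strong X peaks before.

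The gene lists were compared with other genes separately for peaks that held TTGCGAAA and for those that did not. The difference between these sets of peaks was not tested list by list. At ribosomal protein, translation factor, synthetase and respiration genes together, 8 of 60 peaks held the word, against 61 of 441 other promoter peaks. A permutation test within strength quartiles gave p = 0.88. By peaks with the word, aminoacyl-tRNA synthetase genes had 4 of 32 members next to such a peak (12.5%, exact adjusted p = 4.6e-04), p38 immunity genes 2 of 20, cebp-1 and nipi-3 (exact adjusted p = 0.046), bZIP genes 2 of 29, cebp-1 and xbp-1 (exact adjusted p = 0.048), endoplasmic reticulum stress genes 2 of 22, xbp-1 and pdi-6 (exact adjusted p = 0.046), and ribosomal protein genes 3 of 79 (exact adjusted p = 0.046). By peaks without the word 5 lists were enriched, those of translation factors (11 of 42, exact adjusted p = 2.9e-07) and the mitochondrial unfolded protein response (4 of 20, exact adjusted p = 0.013), the ribosomal protein genes (29 of 79, exact adjusted p = 3.1e-23), the mitochondrial respiration genes (12 of 57, exact adjusted p = 6.3e-07) and the heat shock genes (7 of 22, exact adjusted p = 1.4e-05). The p38, bZIP and endoplasmic reticulum calls rest on 2 genes each, and the bZIP call shares cebp-1 with the first and xbp-1 with the last. By peaks with the word, the translation factor, mitochondrial respiration and heat shock lists did not pass.

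Of the 25 strongest peaks, 2 lay next to F-box genes, 1 at fbxc-19 and fbxa-3 and 1 at fbxa-37. Whether F-box genes were more frequent among the strongest peaks was not tested. Over all 322 fbxa, fbxb and fbxc genes, 15 were occupied (4.66%, interval 2.63 to 7.57%) against 3.33% of other genes, which did not pass Fisher's exact test (p = 0.21), while counting genes that share a summit once gave p = 0.044. Of the 15, 4 had a peak with TTGCGAAA, fbxc-19, fbxa-3, fbxa-37 and fbxb-58, which did not pass either (exact p = 0.070).

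A stretch without any peak surrounded zip-2. In the lists used here it ran from 801303 to 861692 on chromosome III in replicate 1 (60390 bp, the 8th longest of 29994 stretches between peaks, whose median was 1377 bp) and from 802108 to 861970 in replicate 2 (59863 bp, the 6th of 28778). The pooled list had 60030 bp there, the 27th longest of 24663, with 15 protein-coding gene starts. What emptied the stretch was not tested, so it does not show that the protein was absent. Around unc-119 replicate 2 had 21682 bp without a peak.

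X held more peaks than its length gives, with a ratio of 1.40 (interval 1.23 to 1.57). A higher background of weak peaks on X was argued against as the whole cause, since against relaxed peaks the ratio was still 1.23 (exact adjusted p = 0.0025). The tRNA and other small RNA genes on X are a candidate source of the excess. Without peaks next to them the ratio was 1.12 (interval 0.948 to 1.30), and its call ended because the ratio fell, besides 659 peaks being fewer than 855. The series has 1 group, so no biological difference between groups was tested as an explanation.

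The strong X peaks form a separate pattern. In the strongest quartile 45 of 61 X peaks lay over 1000 bp from a protein-coding gene start, against 35 of 153 autosomal peaks. Sequence repeated in the assembly was argued against, since 0% of the 45 (upper limit 7.87%) held under 50% unique 31-mers. Such peaks were rare in the whole IDR set, at 8 of 855. Whether recruitment elements of the dosage compensation complex account for 50% or more of the 45 stays open. The 12-base element TCGCGCAGGGAG lay in 26.7% of the 45 (interval 14.6 to 41.9%) with up to 2 mismatches. With up to 4, a loose match that chance often gives, it lay in 27 of the 45, against 14 of the 35 autosomal peaks. The stricter share lies below 50%, but how many sites that match misses was not measured, so neither count decides. With up to 2 mismatches the element lay in 2.86% of the 35 autosomal peaks and in 0.483% of relaxed X peaks. It lay in 9.48% of all X and 0.932% of all autosomal IDR peaks, and on X in 24.6% of the strongest and 2.17% of the weakest quartile. However, the element was chosen after its 8-mers, such as CGCAGGGA in 7 of the 12 X peaks among the strongest 25, had been seen. Small RNA genes lay within 500 bp of 37.8% of the 45 (interval 23.8 to 53.5%), which leaves their part open.

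Ribosomal protein, translation factor, aminoacyl-tRNA synthetase and mitochondrial respiration genes together had 63 of 210 members occupied. Whether open promoters that give weak peaks in any case are the whole cause stays open. Among genes with a relaxed peak the odds ratio was 7.92 (63 of 164 against 7.30% of others, Fisher's exact p = 2.3e-28). Over all genes it was 13.5. The restriction kept all occupied genes and removed only others. An excess would have remained even had all 210 of these genes held a relaxed peak, so the test could not decide. Relaxed peaks do not grade how open a promoter is, so the test cannot speak to the most open ones. The exact word TTGCGAAA was argued against as the source of the peaks at the ribosomal protein, translation factor and respiration genes, since by peaks without it the odds ratio was 15.1 (52 of 178, exact p = 1.3e-37), against 14.3 by all peaks. At the aminoacyl-tRNA synthetase genes its part stays open: without it the odds ratio was 3.48 (3 of 32, exact p = 0.065), against 8.14 by all peaks (7 of 32), and the genes were too few to decide. Unspecific enrichment at highly transcribed genes may also contribute and was not tested, for want of a profile of transcription or of another factor.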
